A study of Mus musculus with 6 samples.

How the data were processed

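The series compares RNA from the presomitic mesoderm level of 9.5 days post coitum mouse embryos, in 3 wild-type pools and 3 pools homozygous for the Dll3 neo allele, on Affymetrix MOE430A arrays, per the labels. The pools are biological replicates per the series design text. How many embryos each held is not given in the sources used here.

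The deposited values are linear ratios. From the values, each probe set was divided by its own median over the 6 arrays: the median is 1 within 0.0011 for 92.8% of the 22626 probe sets tested, below 1 for 1640, where a floor appears to have been used in place of the median, and above 1 for 0. RMA and MAS5 are named in the submitters' processing notes without role or order, so the summarisation, the background step, the normalization between arrays and the absolute level stay unknown. Brightness could therefore not be used to filter or weigh probe sets.

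The design written down before the data were examined named log2(value + 32) for linear values. That offset was meant for intensities and flattens ratios near 1, so log2 of the ratio was used without an offset, and this departure was made after the unit of the values was known. The planned offset and the offsets 1 and 100 are given as alternatives. No further normalization was applied. The 64 Affymetrix control probe sets were left out of the tests, which left 22626 of 22690. By the platform's annotation, 20380 of these have 1 gene symbol, 691 have several and were not used to name a gene, and 1555 are unnamed here. Symbols were updated by Entrez ID through a RefSeq gene table of assembly GRCm38.p6, in which 20364 of 21084 entries matched. That table served for names and for which genes neighbour each other, and no coordinates are given because the files name no build.

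Genotypes were compared for each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Differences are mutant minus wild type on the log2 scale, and folds are 2 to that power. With 3 against 3 pools an exact permutation test of a single gene cannot go below 0.10, so none was used. Each gene entered the list tests by 1 probe set, the one with the highest mean log2 ratio over the arrays, for 12393 genes. This rule was fixed for intensities, and on ratios it does not pick the brightest probe set. It ranks probe sets by the same ratios that are tested, so it favours those with high values in single pools. The mean of all probe sets of a gene was the alternative. The 28 gene lists, 16 of pathways and 12 of tissues and sex, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. Members were also adjusted over the list alone.

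Named genes followed a rule fixed before the data were examined: Dll3, 12 genes per direction without overlap between genotypes (those past the threshold first, then by smallest p, the latter said not to have passed), 2 to 4 genes per list, and 28 genes of the clock and of segmentation. Heart muscle, skeletal muscle and collagen lists, the genes that mark single pools, the choice of windows around Dll3, and the bounds of 0.25 for giving a gene's value without 1 pool and of 0.1 for other probe sets near 0 came after the values were seen.

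The test was run on simulated data, independent noise for 22626 probe sets in 6 arrays with 200 changed. It recovered 0%, 67% and 92.5% of those changed by 1.5-fold, 2-fold and 3-fold, with 0, 4 and 5 false calls, called a shifted list and called 0 of 28 unshifted lists. Real arrays shared structure that this simulation leaves out. With fewer changed probe sets the adjustment would also be stricter than with 200. Alternatives were quantile normalization, centring each array on its median, the offsets, filters on the mean, and a variance trend and robust variances in eBayes. Others were array weights, no variance moderation, the replicate number as a block, and leaving out each pool. The trend followed the mean log2 ratio of a probe set, which is not its intensity. Added after seeing the data were the first residual component as a covariate, a filter on medians below 1 and the lateral plate list without heart genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.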

Results

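Gene expression was measured in the presomitic mesoderm level of mouse embryos at 9.5 days post coitum, the unsegmented tail tissue from which somites form. The dissected tissue held all germ layers, so neural, gut, surface and vascular cells were sampled together with the mesoderm. Wild-type embryos were compared with embryos homozygous for the neo allele of Dll3, a divergent Notch ligand of the segmentation clock. There were 3 biological replicate pools of each genotype, each hybridised to 1 array, and 22626 probe sets were tested. The number of arrays, 6 in all, limits the precision of every value. Each value is a ratio of a probe set to its own median over the 6 arrays, so it compares pools for 1 probe set and carries no absolute level. The median ratio of the wild-type arrays was 0.985, 0.994 and 1.001 in pools 1, 2 and 3, and that of the mutant arrays was 0.985, 1.01 and 0.995.

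The comparison of genotypes asked which genes of the presomitic mesoderm depend on Dll3. Dll3 itself, read by its single probe set 1449236_at, was the 1 probe set that passed the test over all probe sets, and it fell. Its ratio was 1.70 ± 0.278 (SD, n = 3) in the wild type and 0.498 ± 0.0341 (SD, n = 3) in the mutant, a 3.39-fold lower level. The log2 difference was -1.76 (SE 0.14, limma adjusted p = 0.00691), and all 3 mutant pools lay below all 3 wild-type pools. Where this probe set lies relative to the altered part of the gene is not known here, so the drop checks the sample labels only as far as the probe set reads the altered transcript. The call was lost without wild-type pool 2 (adjusted p = 0.0757) and without mutant pool 1, 2 or 3 (adjusted p = 0.0924, 0.0699 and 0.0627), while the log2 difference stayed between -1.87 and -1.64 in the sets of 5 pools. It was also lost on the log2(value + 32) scale written down before the values were seen (adjusted p = 0.271), on log2(value + 100) (adjusted p = 0.274) and without variance moderation (adjusted p = 0.9999).

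**Figure D1:**
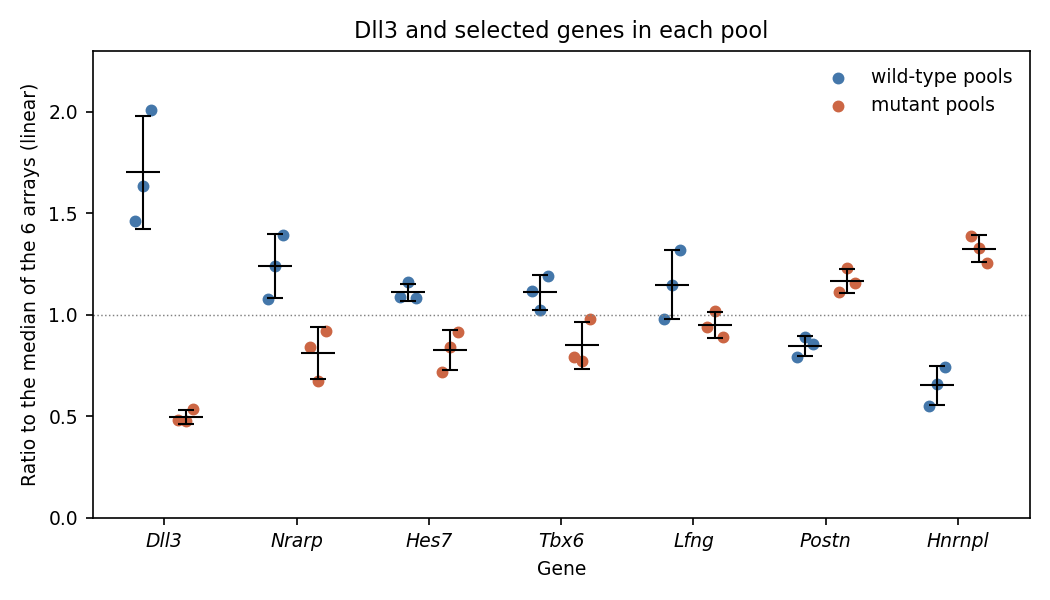
Ratio to the median of the 6 arrays (linear axis) for 7 genes in the 3 wild-type and 3 mutant pools. Points are pools, and bars give the mean and SD of each genotype. Dll3 lies at 1.70 ± 0.278 in the wild type and 0.498 ± 0.0341 in the mutant, and of the 7 genes Dll3 alone passed the test over all probe sets.

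No other probe set passed in either direction. In limma, 262 probe sets reached an unadjusted p under 0.05, of which 138 were higher and 124 lower in the mutant, where chance alone would give about 1131. This count was 650 without wild-type pool 1, 718 without wild-type pool 3 and 168 without mutant pool 2. The 3 mutant and 3 wild-type values did not overlap for 1139 probe sets, or 5.03%, below the 10% expected by chance. Of these, 14 differed by at least 1.5-fold, 5 higher and 9 lower in the mutant. On simulated independent noise the same test recovered 67% of 200 probe sets changed by 2-fold and 0% of those changed by 1.5-fold. The adjustment is stricter when fewer probe sets change, so these shares do not tell how often a lone 2-fold change would be found here.

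The probe set ranked second was that of Hnrnpl, a splicing regulator whose gene is a close neighbour of Dll3. Its ratio was 0.652 ± 0.0953 (SD, n = 3) in the wild type and 1.32 ± 0.0666 (SD, n = 3) in the mutant, 2.05-fold higher (adjusted p = 0.233 over all probe sets). Every other gene named from here on had an adjusted p of 0.9999 over all probe sets and is given by its values alone, unless a list-wise test is stated. Leaving out 1 pool moved the log2 difference by over 1.5 times for 54 of 91 such probe sets, and for the 19 of at least 0.25 in size that became smaller by that much the value without the pool follows the gene. The bound was applied before rounding, so genes just under it, such as Cldn7 (-0.248) and Egr1 (0.245), carry no such value whether or not they moved. The genes ranked next with higher mutant values and no overlap between genotypes were Bcat2, a mitochondrial branched-chain aminotransferase (log2 difference 0.71), the secreted kinase gene Pkdcc (0.46), the matrix gene Postn (0.46), Tex261 (0.42) and Ptov1 (0.44). They were followed by Anxa6 (0.47), the Notch-related transmembrane gene Dlk1 (0.48), the fibrillar collagens Col3a1 (0.72) and Col1a1 (0.49), Crip1 (0.43) and the nuclear pore gene Nup62 (0.54). With lower mutant values and no overlap, the leading genes after Dll3 were Nrarp, a feedback inhibitor of Notch signalling (-0.65 for probe set 1417985_at), the BMP effector Smad5 (-0.53), and Hes7, a repressor that oscillates with the segmentation clock (-0.43). Lin7c (-0.69, and -0.44 without mutant pool 2), Nudt19 (-0.53), Pja1 (-0.39), Cdv3 (-0.42), Gtpbp4 (-0.37), Tnfrsf19 (-0.63), Nap1l2 (-0.40) and Hspa4 (-0.41) completed this set. Of these 24 genes, 16 had another probe set, and for 3 of them, Nup62, Cdv3 and Smad5, at least 1 other probe set had the opposite sign. For 9 of the 16 another probe set lay within 0.1 of 0 on the log2 scale: Tnfrsf19 (about 0.00), Tex261 (0.04), Nudt19 (-0.06), Ptov1 (0.07), Pkdcc (0.08), Gtpbp4 (-0.08), Anxa6 (0.09), Cdv3 (0.08) and Smad5 (0.06).

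Notch target genes were lower in the mutant as a group. Of 17 measured members 13 were lower by sign, the median log2 difference was -0.12, and the list passed camera with its preset correlation (adjusted p = 6.14e-05). It did not pass with an estimated correlation (adjusted p = 0.189 with an estimated correlation). The pool medians of its members were 0.01, 0.02 and 0.18 in the wild type and -0.05, -0.02 and -0.11 in the mutant. Wild-type pool 3 was as high in some lists that did not pass, such as cell cycle genes (0.18) and glycolysis and hypoxia genes (0.17). It was low in others, such as the somite, dermomyotome and sclerotome list (-0.22). With the preset correlation, splits of the arrays that mix the genotypes also passed lists, up to 8 of the 28 against 5 for the genotypes. The median of the Notch targets was -0.07 without mutant pool 2 and -0.07 without mutant pool 3, and their call with the preset correlation stayed without each pool in turn. The call also stayed with the mean of all probe sets of a gene (median -0.06) and with array weights (median -0.08). No member passed over all probe sets, and 2 fell when adjusted over the list alone. Nrarp, by its probe set 1417986_at, fell from 1.24 ± 0.157 to 0.812 ± 0.127 (SD, n = 3 each), 1.53-fold lower (adjusted p = 0.0432 over the list alone), and its other probe set gave 1.57-fold. Hes7 fell from 1.11 ± 0.0419 to 0.826 ± 0.0990 (SD, n = 3 each), 1.35-fold lower (adjusted p = 0.0490 over the list alone). The Nrarp call was lost without wild-type pool 2 or 3 (adjusted p = 0.171 and 0.0687) and without mutant pool 1 or 2 (0.107 and 0.126). The Hes7 call was lost without any 1 pool except mutant pool 3 (adjusted p = 0.0969, 0.239 and 0.0687 without wild-type pools 1, 2 and 3, and 0.237 and 0.126 without mutant pools 1 and 2). Other Notch targets and ligands had smaller values, with log2 differences of -0.27 for Lfng, the glycosyltransferase that modulates Notch in the clock (-0.16 without wild-type pool 3), -0.20 for Hey1, -0.23 for Hes1, -0.12 for Hes5, -0.18 for Mesp2 and -0.15 for Dll1. Hey2 (0.02), whose median lay under the floor of the file, and Heyl (about 0.00) hardly differed.

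Among Notch pathway components, 18 of 32 measured genes were lower and 14 higher by sign, and the list did not pass (adjusted p = 0.323). Dll3 was its 1 member that fell, both over all probe sets and when adjusted over the list alone. Dtx3, a Deltex family gene, had a log2 difference of 0.30, and the receptor gene Notch1 had -0.06.

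The list of posterior presomitic mesoderm and tail bud genes had the largest shift of the 28 lists. Of 20 measured members 19 were lower in the mutant by sign, with a median log2 difference of -0.24 (camera adjusted p = 1.84e-12), and with an estimated correlation it did not pass (adjusted p = 0.211 with an estimated correlation). With array weights, which rest almost wholly on wild-type pool 2 in that genotype, the median was -0.05 and the call stayed (adjusted p = 0.00917). The genotypes did not separate pool by pool: the median log2 ratio of its members was 0.11, -0.02 and 0.30 in wild-type pools 1, 2 and 3 and -0.13, -0.13 and 0.02 in mutant pools 1, 2 and 3. No member passed over all probe sets or when adjusted over the list alone. Besides Hes7, the member with the smallest p was Tbx6, the T-box gene that specifies paraxial mesoderm, at 1.11 ± 0.0857 in the wild type and 0.849 ± 0.113 in the mutant (SD, n = 3 each). Its 3 mutant values lay below its 3 wild-type values. Further members were Cyp26a1, which degrades retinoic acid in the tail bud (log2 difference -0.39, and -0.17 without wild-type pool 3), Msgn1 (-0.19), Fgf8 (-0.20, and -0.02 without wild-type pool 3) and Wnt3a (-0.15).

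Cyclic genes of the segmentation clock, 21 of 29 lower by sign, had a median log2 difference of -0.04 and passed camera (adjusted p = 0.00411), but not with an estimated correlation (adjusted p = 0.549 with an estimated correlation). The genotypes overlapped, with pool medians of 0.02, -0.03 and 0.18 in the wild type and -0.04, 0 and -0.05 in the mutant. Without wild-type pool 3 the median log2 difference was 0.02 and the call was lost (adjusted p = 0.684). It was also lost with quantile normalization (median -0.03, camera adjusted p = 0.0721) and with array weights, where the median turned to 0.03 (camera adjusted p = 0.632). The median was -0.10 without wild-type pool 1, -0.10 without wild-type pool 2, -0.06 without mutant pool 2 and -0.07 without mutant pool 3, where the call stayed. No member passed over all probe sets or over the list alone. Nrarp and Hes7 had the smallest p in this list too. Both are also Notch targets, as are Hes1, Hes5, Hey1, Hey2, Lfng and Id1, so the calls of these lists are not independent. Of the members singled out in advance, the log2 difference was -0.07 for Axin2, -0.10 for Nkd1, -0.15 for Dkk1, -0.16 for Dusp6, -0.03 for Spry2 and -0.04 for Snai1. The 16 members not singled out ran from -0.26, the 1 among them without overlap between genotypes, to 0.25 for Egr1. In order of size, the middle values of these 16 were -0.0020 and -3.87e-04.

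**Figure D2:**
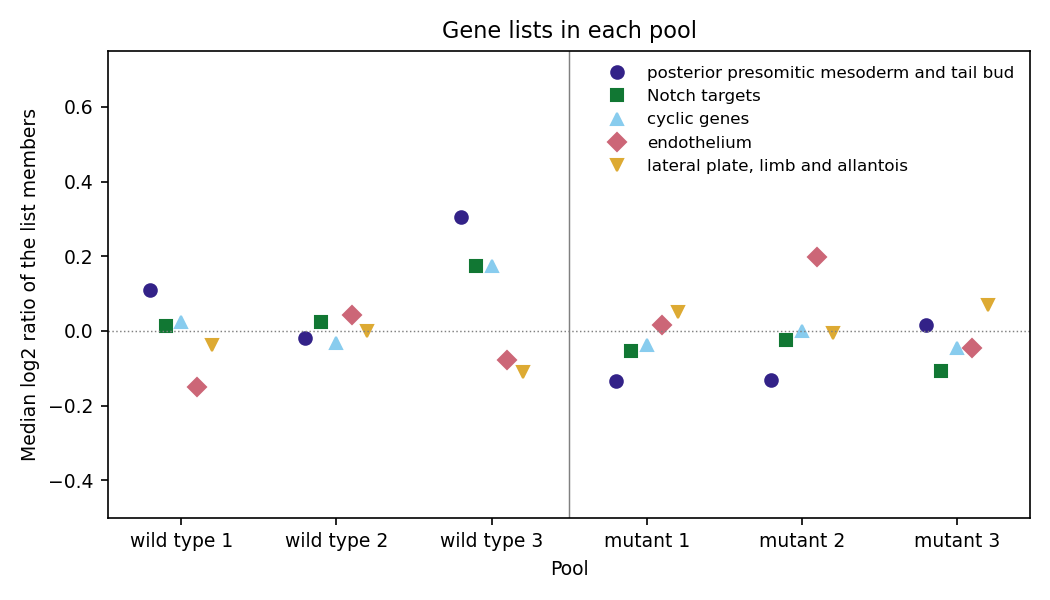
Median log2 ratio of the measured members of the 5 lists that passed camera with its preset correlation, in each of the 6 pools. Each marker is 1 list in 1 pool, and the vertical line parts the wild-type from the mutant pools. The posterior list reached 0.30 in wild-type pool 3, and its median was higher in mutant pool 3 (0.02) than in wild-type pool 2 (-0.02).

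Genes of the anterior presomitic mesoderm and of segment polarity showed no shift as a list, with 11 of 23 lower and 12 higher by sign (adjusted p = 0.643). Uncx, a marker of the posterior somite, had a log2 difference of 0.35 and Meox1 had 0.35 (0.21 without wild-type pool 1), while Tbx18 had 0.20, Pcdh8 0.23, Epha4 -0.07 and Cer1 about 0.00. The somite, dermomyotome and sclerotome list had 16 of 24 members higher by sign, Pax3 (0.27, and 0.02 by its other probe set) among them, and did not pass (adjusted p = 0.0580). Of the 28 genes of the clock and of segmentation singled out in advance, 26 were measured, Ripply2 and T not being analysed here, and 22 were lower and 4 higher in the mutant by sign. The lower genes include Cer1 (about 0.00), Heyl (-0.0027) and Spry2 (-0.025), which hardly differed. With array weights Nkd1, Dkk1, Epha4, Spry2, Axin2 and Snai1 turned to higher.

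The other pathway lists did not pass. Of the 67 genes named beyond the leading ones 27 had another probe set, which had the opposite sign for 4 and lay within 0.1 of 0 for 13. Wnt pathway genes (20 of 33 lower, adjusted p = 0.643) included Tcf7l1 (log2 difference 0.34) and Sfrp1 (0.28), and FGF pathway genes (12 of 20 lower, adjusted p = 0.515) included Egr1 (0.25) and Spred1 (-0.21). Retinoid genes (10 of 16 higher, adjusted p = 0.668) included Rarb (0.31), and Hox genes (19 of 31 lower, adjusted p = 0.430) included Hoxa9 (-0.35, and -0.12 without wild-type pool 3; -0.13 by its other probe set) and Hoxb1 (-0.28, and -0.09 without wild-type pool 3). Adhesion and matrix genes of the somite (19 of 28 lower, adjusted p = 0.0936) included the fibronectin receptor gene Itga5 (0.29, and 0.18 without wild-type pool 3) and Vcan (-0.32, and -0.18 without wild-type pool 1 or mutant pool 2). Cell cycle genes (24 of 38 lower, adjusted p = 0.432) included Cdkn1c (0.25) and Mcm4 (-0.35, and -0.14 without wild-type pool 3; -0.02 by its other probe set), and p53 target and apoptosis genes (16 of 23 lower, adjusted p = 0.426) included Bak1 (-0.29, and -0.12 without wild-type pool 3 and -0.13 without mutant pool 2) and Bcl2l1 (0.19). Glycolysis and hypoxia genes (16 of 26 lower, adjusted p = 0.294) included Ddit4 (-0.60, and -0.40 without wild-type pool 3 and -0.26 without mutant pool 2) and Slc2a3 (-0.21). Immediate early and heat shock genes (14 of 27 lower by sign, with a mean of 0.04, adjusted p = 0.430) included Hspb1 (0.46, and 0.16 without mutant pool 1) and Jund (0.26, and 0.14 without mutant pool 2).

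Genes that neighbour Dll3 on its chromosome did not shift as a list (18 of 34 higher, adjusted p = 0.397). Hnrnpl was the 1 member that rose when adjusted over the list alone (adjusted p = 6.99e-04), and it stayed past the threshold without each pool in turn. Ppp1r14a, a phosphatase inhibitor gene, had a log2 difference of -0.60 with overlapping values (-0.39 without wild-type pool 3).

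Markers of the other tissues in the dissected level were compared in the same way. Endothelium genes were higher in the mutant as a group, 17 of 22 by sign with a median log2 difference of 0.11 (camera adjusted p = 7.02e-04), but not with an estimated correlation (adjusted p = 0.549 with an estimated correlation). The call was lost without wild-type pool 1 (median 0.06, adjusted p = 0.286), while the median was 0.06 without mutant pool 2 and 0.17 without wild-type pool 2, where it stayed. The genotypes overlapped: the median log2 ratio of the members was -0.15, 0.04 and -0.08 in wild-type pools 1, 2 and 3 and 0.02, 0.20 and -0.04 in mutant pools 1, 2 and 3. Its leading members were the receptor gene Tie1 (0.31, and 0.20 without mutant pool 2) and the sialomucin gene Emcn (0.31, and 0.15 without wild-type pool 1). Genes of lateral plate, limb and allantois mesoderm were also higher, 18 of 25 by sign with a median of 0.11 (camera adjusted p = 7.02e-04), again not with an estimated correlation (adjusted p = 0.189 with an estimated correlation). This call was lost without wild-type pool 3 (median 0.10, adjusted p = 0.167), and without mutant pool 1 it stayed with a median of 0.05 (adjusted p = 0.0179). Here too the genotypes overlapped, with pool medians of -0.04, 0 and -0.11 in the wild type and 0.05, -0.0043 and 0.07 in the mutant. Postn rose when adjusted over this list alone, from 0.846 ± 0.0499 to 1.17 ± 0.0604 (SD, n = 3 each; adjusted p = 0.0490), a call lost without any 1 of the 6 pools (adjusted p from 0.0541 to 0.213). The cardiac and gut transcription factor gene Gata5 had a log2 difference of 0.38 (0.22 without mutant pool 1). Mutant pool 1 also held high values of heart muscle genes, a median of 4.47-fold above the other pools for the 15 picked because they were high there and 1.33-fold for 27 others.

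The remaining tissue lists did not pass. Visceral yolk sac endoderm genes (15 of 23 higher, adjusted p = 0.0580) included Fgb (log2 difference 0.32) and Amn (0.22), and surface ectoderm genes (15 of 20 lower, adjusted p = 0.0609) included Krt5 (0.17) and Esrp1 (-0.17). Neural progenitor genes (12 of 21 higher, adjusted p = 0.430) included Zic1 (0.32) and Pax3. Early neuron genes (13 of 24 higher by sign, with a mean of -0.07, adjusted p = 0.432) held Dll3, which fell, and Tubb3 (0.24). Notochord and floor plate genes (7 of 13 higher, with a mean of -0.01, adjusted p = 0.734) included Sox9 (0.14) and Cldn7 (-0.25), and gut endoderm genes (12 of 22 lower, adjusted p = 0.432) included Gata4 (0.36, and 0.23 without wild-type pool 3 and 0.16 without mutant pool 1, the pool with the heart muscle genes) and Cldn6 (-0.18). Intermediate mesoderm genes (7 of 11 higher, adjusted p = 0.323) included Wt1 (0.27) and Gdnf (0.25). Primitive red blood cell genes (11 of 19 lower, adjusted p = 0.542) included Alas2 (0.17, and 0.0077 without mutant pool 1) and Slc4a1 (0.17, and -0.0075 without mutant pool 1), and primordial germ cell and pluripotency genes (10 of 16 lower, adjusted p = 0.426) included Alpl (-0.21) and Kit (-0.20). Sex-linked genes (2 of 4 lower, with a median of 0.02, a mean of -0.04 and adjusted p = 0.786) included Xist (-0.33, and 0.07 without wild-type pool 1 and -0.15 without mutant pool 3) and Kdm5d (0.09).

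Single pools stood apart within their genotype. In mutant pool 1, 37 probe sets were over 2-fold above the other 5 pools, led by heart muscle genes: the ratio of the atrial light chain gene Myl7 was 19.5 there and between 0.823 and 1.05 in the other pools, that of the troponin gene Tnnt2 was 16.4, and that of the cardiac actin gene Actc1 was 9.93. In mutant pool 2, 108 probe sets were over 2-fold below the other pools, led by Grb10 (ratio 0.0663) and Pdia3 (0.0936). Where the gene is named, its other probe sets, 126 in all, had a median log2 deviation of -0.04 there against -1.35, so these low values as a set cannot be read as low expression of the genes. In wild-type pool 3, 52 probe sets were over 2-fold above. The deviations of wild-type pools 1 and 3 from the mean of their genotype had a correlation across probe sets of r = -0.88, against 0.17 for pools 1 and 2 and -0.61 for pools 2 and 3, and the mutant pairs had -0.59, -0.46 and -0.44. Deviations of 3 unrelated pools of equal spread from their own mean correlate at -0.5, so a negative value by itself shows no shared structure. The 3 deviations of a genotype sum to 0, so these correlations only restate the spreads of the pools. In the wild type the spreads were unequal, with residual SDs of 0.18, 0.11 and 0.22 in pools 1, 2 and 3. Xist was highest in wild-type pool 1 and mutant pool 2 by probe set 1427262_at (ratios 2.02 and 2.27), where the Y-linked gene Eif2s3y was lowest (0.487 and 0.674). These differences ran across the genotypes.

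**Figure D3:**
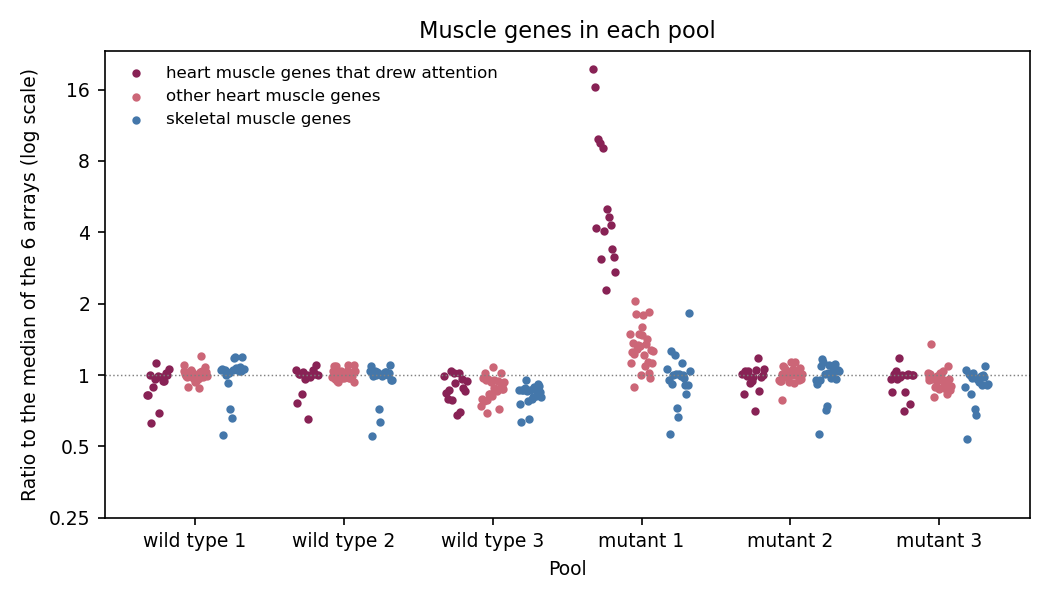
Ratio to the median of the 6 arrays (log axis) of 15 heart muscle genes that drew attention, 27 other heart muscle genes and 20 skeletal muscle genes in each pool. Each point is 1 gene, the mean of its probe sets. In mutant pool 1 the heart genes reach 19.5, while the median of the skeletal genes lies at 1.0013-fold of the other pools.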

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

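Of the 64 control probe sets, which the comparison of genotypes does not use, 2 had all 3 mutant pools above all 3 wild-type pools, where chance would give about 3.2. The log2 difference between the genotype means was 0.37 for AFFX-MURINE_b1_at and 0.14 for AFFX-r2-Bs-dap-5_at. Control probe sets lower in all mutant pools were not counted. Some controls differed widely within a genotype: AFFX-18SRNAMur/X00686_5_at ran from 0.475 to 2.695 in the wild type and from 0.377 to 1.576 in the mutant. Others hardly differed, such as AFFX-GapdhMur/M32599_M_at, which ran from 0.968 to 1.009 over all pools.

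The tests of the next 3 patterns were all chosen after the pattern had been seen. In mutant pool 1, 15 heart muscle genes were a median of 4.47-fold above the other pools. A whole-array shift of the deposited values is argued against, since the median log2 ratio of all probe sets there was -0.023. Whether the array was shifted before the submitters' processing cannot be seen, because the normalization between arrays is unknown. The 20 skeletal muscle genes did not share the rise, with a median of 0.0018 and a median absolute deviation of 0.19. This cannot exclude skeletal muscle, because it is not known whether these genes are detected here. Myf5, Myh3 and Myh8 had ratios below 1 in every pool. Among 27 heart muscle genes not used to see the pattern, 23 were highest in this pool and the median was 0.41, so heart tissue in this pool is a candidate explanation. Of these, 3 are also lateral plate genes: Gata4 (ratio 1.36) and Tbx5 (1.13) were highest in this pool, while Hand2 (0.892) lay below all 3 wild-type pools. No biological explanation was tested, since 1 pool of 3 cannot be set against the genotype, and the share of this pool in the lateral plate shift stays open: without these 3 that list kept its call with the preset correlation (median 0.11, adjusted p = 8.86e-04), but without mutant pool 1 the median of the whole list fell from 0.11 to 0.05, and the whole list was not called with an estimated correlation (adjusted p = 0.189).

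Of the 100 probe sets with the smallest p, 17, Dll3 included, lie on the chromosome of Dll3, which holds 7.06% of all probe sets, and 5 genes within 200 measured genes of Dll3 on either side had an unadjusted p under 0.01 in limma: Hnrnpl, Nup62, Ptov1 and Bcat2 higher and Nudt19 lower. Whether such clustering arises by chance depends on the window: 1.77% of windows elsewhere held as many with 100 genes on each side and 0% with 200, but 10.1% with 50 and 4.81% with 20; with 10 there were 0 such genes near Dll3, as many as 100% of windows hold. Neighbouring genes are also not independent. Probe mismatch from a flanking segment of another strain would lower mutant values if the probes match the wild-type strain better. Of the 5 genes, 4 were higher (1 of 2 within 100 genes). The strains are not given here, so this direction cannot decide about mismatch, since a better match in the mutants would raise values. For Nup62, 3 other probe sets had the opposite sign. The other probe sets of Ptov1 (0.07) and Nudt19 (-0.06) lay near 0. Probe mismatch stays open, and so does altered expression of the neighbours by the neo allele or by a flanking segment, which was not tested.

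The posterior presomitic mesoderm list was lower in the mutants, with wild-type pool 3 highest and with Cdx2 at 0.274 in mutant pool 2. Neither pool alone accounts for it, since the median was -0.16 without wild-type pool 3 and -0.18 without mutant pool 2, and the call with the preset correlation stayed in both. A smaller share of tail bud tissue in the mutant pools would raise the lists of all other tissues, and 4 of 11 had a median below 0, none of them called, so tissue share and a lower level per cell cannot be told apart here. A difference by genotype stays open as well, because the list was not called with an estimated correlation.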

How the results depend on the processing

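Array medians were already between 0.985 and 1.008, so centring could change little, and the variance trend followed the mean log2 ratio, not intensity. The filter on medians below 1 was added after seeing the data. The count of 1 probe set past the threshold stayed at 1 with median centring, log2(value + 1), the variance trend, robust variances and the filters. It was 2 with quantile normalization (Dll3 and Hnrnpl, the latter at adjusted p = 0.0304), 4 with array weights (Dll3, Hnrnpl, Nrarp and Bcat2) and 2 with the first residual component as a covariate, added after seeing the data (Dll3 and Hnrnpl at adjusted p = 0.0475). The array weights are a poor guide, since their estimation did not converge and gave wild-type pool 2 a weight of 83.9 against 0.756 or less for the others. It was 0 with log2(value + 32), log2(value + 100) and no variance moderation, and without single pools it lay between 0 and 1. The Dll3 log2 difference was -0.052 with the offset 32 and -0.017 with 100, which shrink every difference, -1.76 without moderation, and between -1.87 and -1.64 without single pools; over all alternatives its adjusted p ran from 7.02e-06 to 0.9999. At an unadjusted p under 0.05, limma gave 941 probe sets with the residual component, 3641 with array weights, 461 without variance moderation, 434 with the replicate block and 117 with the filter that keeps the higher means, against 262; without single pools it gave 168 to 718.

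Replicate numbers were not taken to pair the pools: same-numbered pools had residual correlations of 0.21, 0.02 and 0.17, and 4 of 6 pools correlated best with their own number. Most control probe sets named for Bio or Cre set both pools numbered 3 apart. AFFX-BioB-M_at was 0.615 in wild-type pool 3 and 0.612 in mutant pool 3, against 0.965 to 1.531 elsewhere. In the same order, AFFX-BioB-3_at was 0.674 and 0.699, AFFX-r2-Ec-bioB-M_at 0.535 and 0.455, and AFFX-CreX-3_at 0.72 and 0.776, all lowest in these pools. AFFX-BioDn-5_at was highest in them (2.07 and 1.659). Of this group AFFX-BioC-3_at, AFFX-CreX-5_at, AFFX-r2-Ec-bioB-5_at, AFFX-r2-Ec-bioD-3_at and AFFX-r2-Ec-bioD-5_at did not set both apart. Outside it, AFFX-LysX-3_at (0.978 and 1.019, against 0.988 to 1.049) did not either. Whether same-numbered pools shared a processing step is not known. With the replicate block the count of probe sets was 1 and that of lists 7; among the list-wise calls Hes7 (adjusted p = 0.0561) and Postn (0.0661) missed the threshold with it. Over all alternatives run, Hnrnpl kept its list-wise call in 19 of 19, Nrarp in 15 of 20, Hes7 in 10 of 18 and Postn in 9 of 20; the planned filters on a low mean took out Hes7 in both cases and Hnrnpl in the stricter, and the mean of ratios is not brightness.

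The count of 5 lists was 3 with array weights, 0 with an estimated correlation, 0 with fry, 9 with the mean of all probe sets of a gene, and between 3 and 8 without single pools (3 without wild-type pool 3, 8 without wild-type pool 2). With an estimated correlation and with fry the medians were the same, -0.12 for Notch targets, -0.036 for cyclic genes, -0.24 for the posterior list, 0.11 for endothelium and 0.11 for lateral plate, and none passed; the cause was not tested. Testing for changes in either direction, fry passed 2 lists, both holding Dll3. Notch targets kept their call from -0.1805 to -0.0699 without single pools, at -0.058 with the mean of all probe sets and at -0.078 with array weights, and the posterior list kept its own at -0.050 with array weights and from -0.31 to -0.16 without single pools. Offsets shrink these medians too. Cyclic genes also lost their call with quantile normalization (-0.027) and array weights (0.027, the opposite sign), had -0.086 with the filter that keeps the higher means, and ran from -0.096 to 0.015 without single pools. Endothelium (0.033) and lateral plate genes (0.10) lost theirs with array weights, and ran from 0.060 to 0.17 and from 0.047 to 0.13 without single pools.

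Of the 91 other named probe sets, 80 kept their sign without each pool in turn; none of the sign changes concerned a gene past a threshold, and the cause was not tested for these or for the calls above unless stated. Without single pools, log2 differences ran from -0.0075 to 0.33 for Slc4a1, -0.096 to 0.17 for Hey2, -0.15 to 0.035 for Notch1, -0.073 to 0.072 for Heyl, -0.298 to 0.015 for Dkk1, -0.12 to 0.050 for Epha4, -0.59 to 0.075 for Xist, -0.13 to 0.11 for Spry2, -0.12 to 0.0098 for Snai1, -0.071 to 0.048 for Cer1 and -0.051 to 0.24 for Kdm5d. Array weights turned the sign of Nkd1 (0.0062), Dkk1 (0.081), Epha4 (0.042), Xist (0.24), Spry2 (0.069), Axin2 (0.11), Snai1 (0.073) and Kdm5d (-0.084). The mean of all probe sets of a gene turned that of Slc4a1 (-0.035), Heyl (0.028), Spry2 (0.0088), Nup62 (-0.079) and Cer1 (0.041). Quantile normalization turned Spry2 (0.041), and the offsets 1, 32 and 100 turned Cer1 (7.75e-05, 2.76e-05 and 9.36e-06). Signal over background is not known for these ratios.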

Other observations

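The tests on collagen genes were chosen after the values had been seen. Genes of fibrillar matrix and smooth muscle were higher in the mutant: 18 of 20 measured genes by sign, with a median log2 difference of 0.26. The list was drawn up because Col3a1, Col1a1, Postn and Dlk1 ranked high, and the 16 members not named for the genotype comparison had a median of 0.16, 14 of them higher. Acta2, Tagln, Cnn1 and Myl9 were highest in mutant pool 1 (ratios 1.502, 1.42, 1.46 and 1.69), the pool with the heart muscle genes. Mutant pool 1 alone does not account for the shift, since the median of these 16 members without it was 0.16, with 15 of them higher.

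In mutant pool 1 the yolk sac gene Afp was also high, with a ratio of 2.48 by probe set 1416645_a_at, where the other pools lay between 0.669 and 0.719. Other probe sets of Afp were closer to the other pools, at 0.776 for 1436881_x_at.

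In mutant pool 2, the 98 probe sets with 1 gene symbol that were over 2-fold below the other pools had a median log2 deviation of -1.35. The 126 other probe sets of the same genes had a median of -0.04, and 73 of them were below 0. Rtn4 had a ratio of 0.155 there by 1421116_a_at and 1.08 by 1452649_at, while both probe sets of Tkt (0.184 and 0.226) and of Cdx2 (0.274 and 0.409) were low. In wild-type pool 3, the 71 other probe sets of the genes over 2-fold above had a median of 0.28, and 60 were above 0.

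The 6 arrays can be parted into 3 and 3 in 10 ways, too few for a share under 0.05, a comparison planned before it was run. The genotypes gave 1 probe set past the threshold, a count reached by 1 of the 10 splits, their own, and the highest of the others was 0. They gave 5 lists past the threshold with the preset correlation, a count reached by 2 of the 10 splits, and the highest of the others was 8, with wild-type pools 1 and 3 and mutant pool 3 on 1 side. The split of wild-type pools 1 and 2 and mutant pool 1 against the rest had 2813 probe sets at an unadjusted p under 0.05 in limma, against 262 between the genotypes. This points to a structure of the samples or of the arrays other than genotype, and which of these it was stays untested.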
